A study of Mus musculus with 8 samples.

How the data were processed

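The 8 arrays are dual-channel Agilent mouse gene expression arrays of 43790 spots each, 41534 of them non-control and 2256 control. Per the labels' protocols, total RNA was isolated with TRIzol and labelled with Cy3 and Cy5, and each pair of RNAs was hybridised again with the dyes swapped. Per the file headers, the deposited scanner files hold the mean spot intensity and the median local background intensity of each channel, with no normalization. They hold processed intensity values after background subtraction, detrending and dye normalization, all made by Feature Extraction. They also hold a log10 ratio of Cy5 over Cy3, per the file headers, made from the processed signals. The version, read from the header of a 1000 ng/ml array, was 10.5.1.1. The submitters' processing notes name Agilent Feature Extraction with no version. Per the file headers, the 1000 ng/ml pair used a multiplier of 2.6 in the call of a spot as well above background, and no multiplicative detrending. The 6 other arrays used a multiplier of 13, with detrending. The deposited series matrix was tested against the scanner files: its log10 values equal the scanner log ratio, with the sign turned where the named RNA is in Cy3, to within 5e-06.

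Processing from the spots used R 4.3.3 with limma 3.58.1 and the data.table package, version 1.17.8, and figures used Python 3.11.15 with matplotlib 3.10.9. Background was corrected with normexp and an offset of 50, log2 ratios were normalized within each array by loess with control spots at weight 0, and spots marked as outliers (37 to 295 per array) were left out. No spot was saturated. Ratios were turned so that a positive log2 value means higher in the named RNA than in clone 4 without doxycycline. Spots of the same probe (41174 probes) were averaged. Of these probes 33026 had a gene name, from the files or the RefSeq table, and 8148 kept their own. Each name was represented by its probe with the highest mean log2 intensity over all arrays and channels, whatever its ratio, and where another detected probe of a named gene had the opposite sign or a ratio within 0.5 of 0 where the gene passed the size or is named for a test, that is said beside the gene. A feature was tested if its probe was well above background in the same RNA on both arrays of at least 1 comparison: 29464 probes, 20002 features, 15711 of them named. No genome was given, so no coordinates are printed.

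Control and named RNA were assigned from the labels. The 2 arrays of a comparison were averaged into 1 sample, since the labels give no replicate cultures. A mean doxycycline effect (intercept over the 3 doses) and a dose trend (slope on log10 dose) were fitted with limma and moderated by eBayes, with Benjamini-Hochberg adjusted p under 0.05. These tests are two-sided, treat differences between doses as spread and leave out the spread of the control RNA. Single comparisons used a size rule with no test: at least 2-fold (log2 of 1 or more) on both arrays in the same direction. A ratio against an RNA that was not well above background is given as a lower bound against that array's detection level. Gene lists (18, fixed from textbook knowledge before the data were examined) were tested with limma camera at a correlation of 0.01 and adjusted over the lists, and with an estimated correlation. In single comparisons a list's median ratio was placed among 10000 random lists of the same size and intensity. The lists were Pax5-activated, Pax5-repressed, pro-B and pre-B cell, mature B cell and class II, myeloid and granulocyte, T lineage, NK and innate lymphoid, dendritic cell, erythroid and megakaryocyte, mast cell and basophil, stem and multipotent progenitor, stromal feeder cell, DNA replication, mitosis, p53 target and apoptosis, amino acid stress response, glycolysis and interferon response genes.

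Named genes followed a rule fixed before the data were examined: Pax5 first, the 12 highest and 12 lowest features of a test past its threshold or else the 5 smallest p per direction, the 5 highest and 5 lowest features past the size at each dose and the 12 for Pax5sz2, and from each list up to 4 members with the largest mean effect and up to 4 with the largest ratio in Pax5sz2. The part on tests and lists was applied a second time with the 1000 ng/ml sign turned, which was chosen after the ratios were seen. Features named only by an accession, clone, predicted-gene or locus number were counted and not named: 146 of those past the size at 10 ng/ml, 179 at 300 ng/ml, 54 at 1000 ng/ml and 234 in Pax5sz2. Foxo1, Sox4, Id3 and Ighm, and the collagen and fibronectin genes given with their intensity in the closing part, were named after their values were seen. Some genes that the rule names are not reported here.

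The steps were tested on simulated data for 19748 features, with 50 of them changed at each of 4 sizes. The size rule recovered 96% to 100% of changes of log2 1.5 to 4 in each comparison and passed 3, 108, 4 and 3 of 19548 unchanged features at 10, 300 and 1000 ng/ml and in Pax5sz2. The mean effect recovered 84%, 80%, 92% and 92% at log2 1.5, 2, 3 and 4 and passed 18 unchanged features. The simulated spread between doses was that between 10 and 300 ng/ml, without the 1000 ng/ml pair. These shares therefore do not hold for the test over the 3 doses as labelled. The simulated doses varied independently, without the error of a shared control RNA, which would look like a mean effect. For the size rule the simulated spread was that between the 2 technical arrays. The counts of unchanged features passed are therefore no rates of false passes between cultures. The dose trend, with 1 residual degree of freedom, recovered 0% at each size. Camera at the preset correlation passed 1 of 1 list shifted by log2 1 and 0 of 17 unchanged lists, and with an estimated correlation 0 of 1. The genes of these simulated lists varied independently, so the preset correlation was not checked for lists whose genes move together.

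Alternatives fixed beforehand covered background correction (processed signals, offset 16, none), median centring, scaling to an equal median absolute deviation, filters, probes per gene, series-matrix ratios, the size rule, eBayes settings, arrays as samples in a random block, dose scales, and leaving out each array or dose. Turning the 1000 ng/ml sign, and an estimated correlation without a dose, were added after the data were seen. Other splits of the samples were not counted, since the labels give 1 control and there are no groups of 3 samples to compare.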

Results

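Expression was measured in mouse B cell precursors that lack Pax5, the transcription factor that commits progenitors to the B lineage. The cells came from bone marrow and grew with IL-7 on irradiated OP9 stromal cells, a feeder layer. Clone 4 carried a human Pax5 transgene (huPax5) under a doxycycline-dependent promoter together with the transactivator rtTA, and received 10, 300 or 1000 ng/ml doxycycline. Pax5sz2 cells carried rtTA without huPax5 and were labelled as doxycycline-treated, with no dose given. Each of these 4 RNAs was hybridised against RNA labelled as clone 4 without doxycycline (0 ng/ml) on 2 arrays with the dyes swapped, 8 arrays in all. The dose comparisons ask which genes differ with the amount of inducer, and the Pax5sz2 comparison which differ in treated cells without the transgene. Pax5sz2 and clone 4 are labelled as different cells. In that comparison the transgene, doxycycline and differences between the cells therefore cannot be told apart. A comparison thus rests on 1 RNA sample measured on 2 technical arrays. There were no replicate cultures, so single comparisons have no p-value of their own, and every ± is the SD of those 2 arrays. A fit for Pax5sz2 given below borrows the spread of the doses. Between 40.4% and 45.1% of the spots were well above background in a channel of the 1000 ng/ml arrays, and between 59.5% and 75.5% on the 6 others. That call used a multiplier of 2.6 on the 1000 ng/ml arrays and of 13 on the others. These shares, and later calls of an RNA as dim, are therefore not at 1 threshold. The number of arrays limits the precision.

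The direction of the 1000 ng/ml pair was not settled. Its 2 arrays were on rehybridised slides, were scanned earlier and were processed with an older scanner protocol than the other 6, so dose and batch cannot be told apart for it. Across all probes, its ratios ran against those of the 300 ng/ml arrays of the same dye orientation (r = -0.359 with the named RNA in Cy5 and r = -0.46 in Cy3, across genes, which are not independent replicates). The labelled direction was kept, because nothing in the labels gives another. Its counts, and the tests over the 3 doses, are given as labelled and with its sign turned. Other counts and values of this pair are as labelled unless said, and would change sides or sign if turned.

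Pax5 itself was read first. The probe for the mouse coding transcript gave log2 ratios of -0.11 ± 0.059 at 10 ng/ml, 0.23 ± 0.073 at 300 ng/ml and -0.27 ± 0.032 in Pax5sz2. At 1000 ng/ml the control RNA was well above background for it and the named RNA was not. A probe for a complementary DNA clone assigned to the Pax5 locus gave 2.66 ± 0.20 at 10 ng/ml, 2.36 ± 0.055 at 300 ng/ml and 3.02 ± 0.19 in Pax5sz2, and was in neither RNA well above background at 1000 ng/ml. The transgene is human and the mouse gene is knocked out, so these mouse probes may read neither. They do not check the labels.

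At 10 ng/ml, the features past the size included interferon-induced genes and a few stromal genes, higher than in clone 4 without doxycycline. Of 17 tested members of the interferon response list, 9 were at least 2-fold higher on both arrays and 0 lower. Among them Usp18, the protease that removes ISG15, was at log2 2.94 ± 0.10, Isg15, a ubiquitin-like modifier, at 2.27 ± 0.14, and Ifit3, an antiviral gene, at 1.94 ± 0.059. The list's median was 1.12, at percentile 100 of 10000 random lists of like intensity. Of 20 stromal genes, 3 were higher and 0 lower (median 0.71, percentile 100): the chemokine gene Cxcl12 at 1.45 ± 0.013, the collagen gene Col3a1 at 1.27 ± 0.047 and the adhesion molecule gene Vcam1 at 1.20 ± 0.0024. Other probes of Col3a1 and Vcam1 differed.

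The remaining lists held few such genes at 10 ng/ml. Tyrobp, the gene of the signalling adaptor DAP12 in myeloid and NK cells, was at -1.35 ± 0.15, whereas Cebpb, a transcription factor gene of the myeloid lineage, was at 1.45 ± 0.036, so the myeloid list had 1 of 23 higher and 1 lower. Cd7 was the 1 of 12 dendritic cell genes that was lower (-1.57 ± 0.24), and Cd180 the 1 of 18 mature B cell genes (-1.26 ± 0.33, another probe differing). The stress-induced transcription factor gene Atf3 (1.82 ± 0.19) and the hexokinase gene Hk2 (1.22 ± 0.10) were the only members higher among 18 amino acid stress genes and 16 glycolysis genes. No member of the 11 other lists passed the size. The Pax5-activated list had a median of -0.07 and the Pax5-repressed list of -0.15, and both turned positive with median centring (0.14 and 0.13).

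The highest named features at 10 ng/ml were Usp18, the Pax5 locus probe, the kinesin genes Kifc5b (2.55 ± 0.14) and Kifc1 (2.43 ± 0.36), and Arl15 (2.48 ± 0.025). The lowest were Mitf (-2.49 ± 0.13), L3mbtl2 (-2.42 ± 0.0071), Afap1 (-2.32 ± 0.16), Srrm3 (-2.31 ± 0.067) and the linker histone gene H1f3 (-2.21 ± 0.21). For the first 4 of these the RNA labelled as control had mean log2 levels of 10.67, 13.05, 10.56 and 13.02 here, but 6.68, 9.29, 6.97 and 9.45 on the Pax5sz2 arrays. Arl15 and the 5 lowest genes each had another detected probe that did not show the ratio. That held for 14 of the 18 named genes past the size with another probe. In all, 121 features were at least 2-fold higher on both arrays and 254 lower, of 20002 tested, and the arrays correlated with r = 0.836 across genes. Median centring in place of loess gave 74 higher and 75 lower, Agilent's processed signals gave 405 and 632, and a single array (without replicate 2) gave 691 features.

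At 300 ng/ml, the features past the size included some B lineage targets of Pax5, higher, and some myeloid genes, lower. Of 20 Pax5-activated genes, 8 were at least 2-fold higher on both arrays and 0 lower (median 0.58, percentile 100, and 0.87 with median centring). Blnk, the adaptor of pre-B cell receptor signalling, was at 2.62 ± 0.12, Bcar3 at 1.75 ± 0.028 and Ikzf3, which encodes Aiolos, at 1.28 ± 0.26 with another probe differing. Of 17 Pax5-repressed genes, 6 were lower and 0 higher (median -0.98, percentile 0). Fcer1g, the common signalling chain of Fc receptors, was at -3.40 ± 0.18, the chemokine receptor gene Ccr2 at -2.06 ± 0.021 with another probe differing, Notch1 at -1.53 ± 0.16 and Jchain, the joining chain of antibody polymers, at -1.35 ± 0.24.

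Of 23 myeloid and granulocyte genes, 6 were lower and 0 higher at 300 ng/ml (median -0.47, percentile 0.01, and -0.75 with processed signals). Tyrobp was at -3.39 ± 0.0091, the neutrophil protease gene Ctsg at -2.98 ± 0.12, and Fcgr3, a low-affinity IgG receptor, at -2.70 ± 0.19. Lower members were also 4 of 12 dendritic cell genes (median -0.61), 3 of 18 mature B cell genes (median -0.03, or -0.29 with processed signals), 2 of 9 NK genes (Nkg7 at -2.46 ± 0.43), 2 of 9 mast cell genes (the carboxypeptidase gene Cpa3 at -2.01 ± 0.11), and 1 each of 18 T lineage, 9 erythroid and 12 stem cell genes. None of these lists had a higher member. Interferon genes were again higher, 10 of 17 (median 1.26, percentile 100), with the chemokine gene Cxcl10 at 2.54 ± 0.075 and Isg15 at 2.43 ± 0.18. So were 8 of 20 stromal genes (median 1.00, percentile 100), with Cxcl12 at 1.75 ± 0.28 and the matrix protein gene Sparc at 1.47 ± 0.16. Atf3 (2.28 ± 0.33) and the mitochondrial folate enzyme gene Mthfd2 were higher among 18 amino acid stress genes (median 0.44, percentile 99.98). Hk2 was the 1 of 16 glycolysis genes and Sesn2, with another probe of opposite sign, the 1 of 17 p53 target genes that was higher. No gene of the pro-B, DNA replication or mitosis lists passed the size, Dntt being left out on 1 array (-2.48 on the other, and -2.44 and -2.42 with its other probes), with medians of -0.11 (-0.37 with processed signals), 0.22 and 0.29 (0.43 and 0.53 with median centring).

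The highest named features at 300 ng/ml were the interferon-induced genes Ifi44l (2.84 ± 0.071) and Iigp1 (2.65 ± 0.31), Kifc1 (2.77 ± 0.15), Cplx2, a complexin of regulated exocytosis (2.65 ± 0.039, another probe differing), and Blnk. The lowest were the integrin gene Itgb7 (-3.55 ± 0.26), Nrgn, a calmodulin-binding protein gene (-3.54 ± 0.96), the IL-18 receptor gene Il18r1 (-3.52 ± 0.20), Gbp8 of the guanylate-binding proteins (-3.48 ± 0.42) and Fcer1g. In all, 263 features were higher and 472 lower. The arrays correlated with r = 0.641 across genes, the lowest of the 4 comparisons, and 10 features passed the size with opposite signs. Median centring gave 96 higher and 384 lower, processed signals gave 661 and 1218, and leaving out replicate 2 gave 2260 features, 1787 of them lower. On simulated data with the spread between this comparison's 2 arrays, 108 of 19548 unchanged features passed the rule.

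At 1000 ng/ml as labelled, the members of the Pax5-activated, Pax5-repressed and myeloid lists past the size lay on the other side. Of 20 Pax5-activated genes, 12 were lower and 0 higher (median -1.39, percentile 0), with Blnk at -4.20 ± 0.27, Bcar3 at -3.25 ± 0.36 and Ikzf3 at -3.08 ± 0.48, another probe of Ikzf3 differing. Of 17 Pax5-repressed genes, 9 were higher and 0 lower (median 1.33, percentile 100, and 1.35 to 2.5 over 6 other scalings), with Fcer1g at 4.46 ± 0.046, Jchain at 3.75 ± 0.20, Notch1 at 2.60 ± 0.13 and the chemokine gene Ccl9 at 2.31 ± 0.24. Of 23 myeloid genes, 6 were higher and 0 lower (median 0.44, percentile 100, and 0.45 to 0.82 over those scalings), with Ctsg at 5.14 ± 0.19, Tyrobp at 4.06 ± 0.10 and Fcgr3 at 3.77 ± 0.011. With members against a dim RNA at their lower bound, the medians were -1.22, 1.14 and 0.39. With the sign turned, each of these values and counts changes sides, which is the side of the same lists at 300 ng/ml.

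Other groups at 1000 ng/ml as labelled were lower or higher in part. Of 18 amino acid stress genes, 5 were lower (median -0.70, percentile 0), among them the asparagine synthetase gene Asns (-2.65 ± 0.30) and the stress-induced pseudokinase gene Trib3 (-2.35 ± 0.18). No mitosis or DNA replication gene passed the size, but all 20 mitosis genes were below 0 on both arrays (median -0.71) and 16 of 20 DNA replication genes (median -0.29, or -0.51 with median centring). Higher members were 4 of 18 mature B cell genes (1 lower, Ighm at -1.04 ± 0.011), 4 of 12 dendritic cell, 3 of 9 NK, 3 of 17 p53 target, 2 of 18 T lineage, 2 of 9 mast cell and 2 of 12 stem cell genes (1 lower), and 1 of 9 erythroid and of 17 pro-B genes. The interferon list had a median of -0.05 with 1 of 17 higher (Oasl2), the stromal list a median of -0.10 with 0 of 20 past the size, and the glycolysis list -0.13 (-0.27 with median centring) with 1 of 16 lower.

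The highest named features at 1000 ng/ml as labelled were Ctsg, Il18r1, Fcer1g, Gbp8 (4.32 ± 0.0093) and Spns3 (4.32 ± 0.27). The control signal of Il18r1 was not well above background, so it was at least 23.3-fold higher. The lowest were Cplx2 (-4.73 ± 0.28), Blnk, the sodium pump subunit gene Atp1b1 (at least 14.2-fold lower, its named RNA being dim), the cystathionine gamma-lyase gene Cth (-3.80 ± 0.36) and Bst1 (-3.26 ± 0.10). In all, 387 features were higher and 127 lower as labelled, or 127 higher and 387 lower with the sign turned. The 2 arrays correlated with r = 0.829 across genes. For 60 of the 514 the ratio was a lower bound, since the other RNA was dim. Median centring gave 146 higher and 47 lower, and series-matrix ratios gave 680 and 239.

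**Figure D1:**
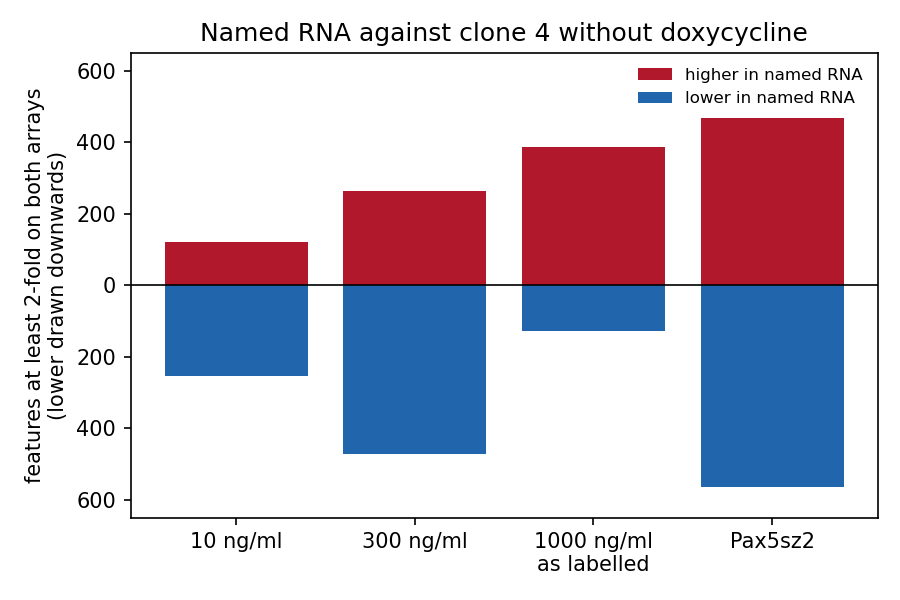
Number of features at least 2-fold higher (upward bars) or lower (downward bars) in the named RNA on both dye-swapped arrays of each comparison (x axis), of 20002 tested. At 10 and 300 ng/ml more were lower (254 and 472) than higher (121 and 263), though 75 and 74 at 10 ng/ml with median centring, and at 1000 ng/ml as labelled more were higher (387) than lower (127).

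**Figure D2:**
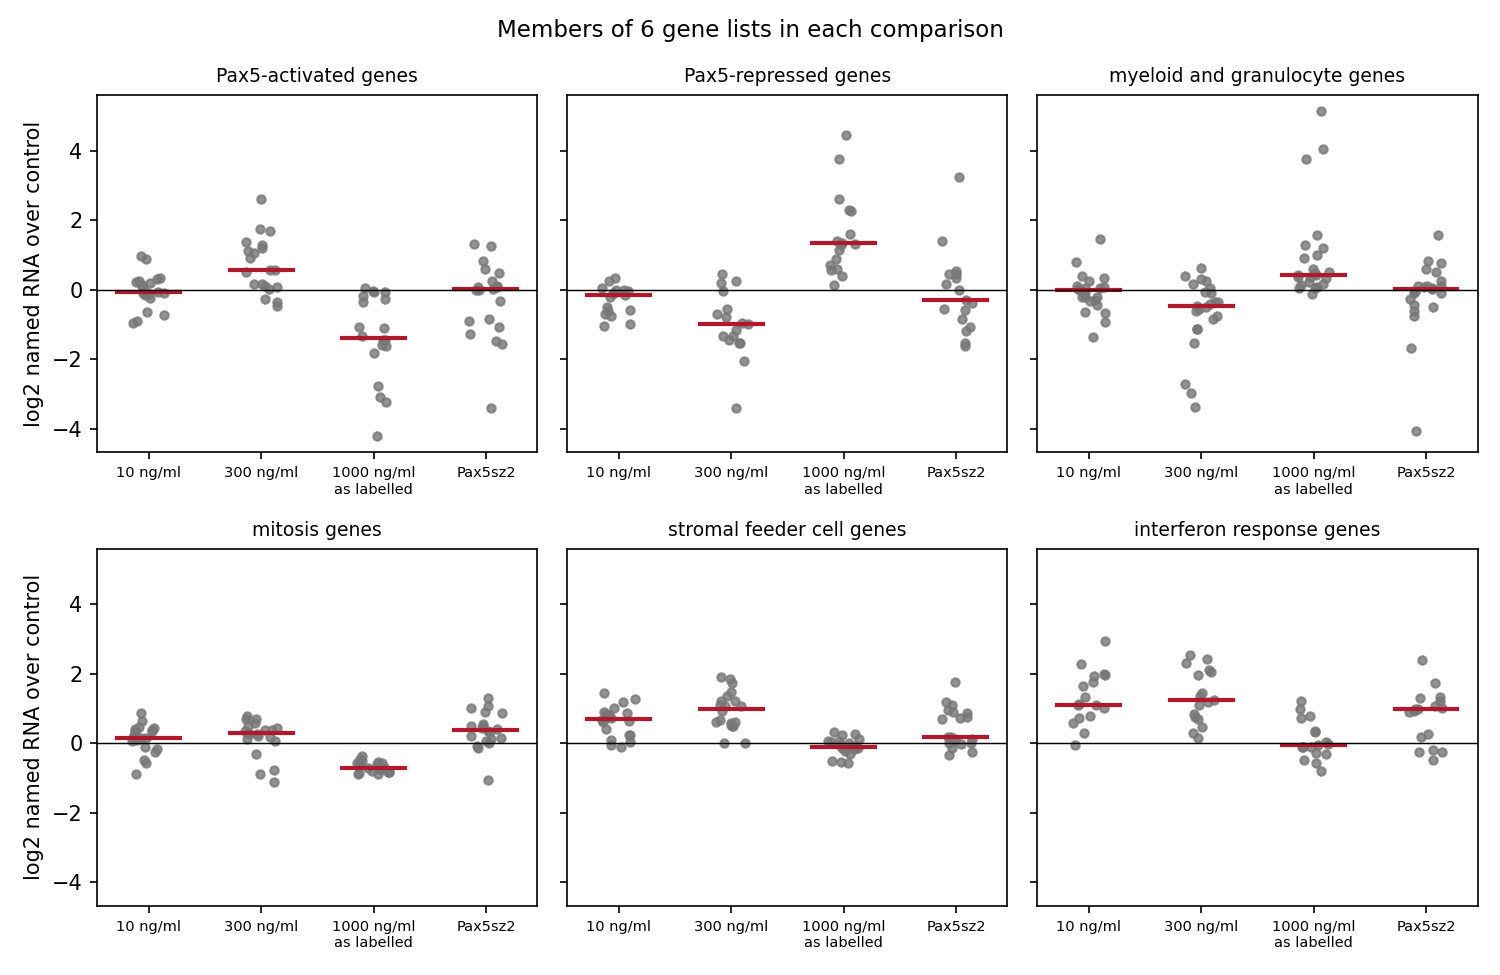
Log2 ratio of the named RNA over clone 4 without doxycycline (y axis) of the tested members (points) of 6 gene lists in the 4 comparisons (x axis), with the list median as a line. Pax5-activated genes have a median of 0.58 at 300 ng/ml and -1.39 at 1000 ng/ml as labelled, and Pax5-repressed genes of -0.98 and 1.33.

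**Figure D3:**
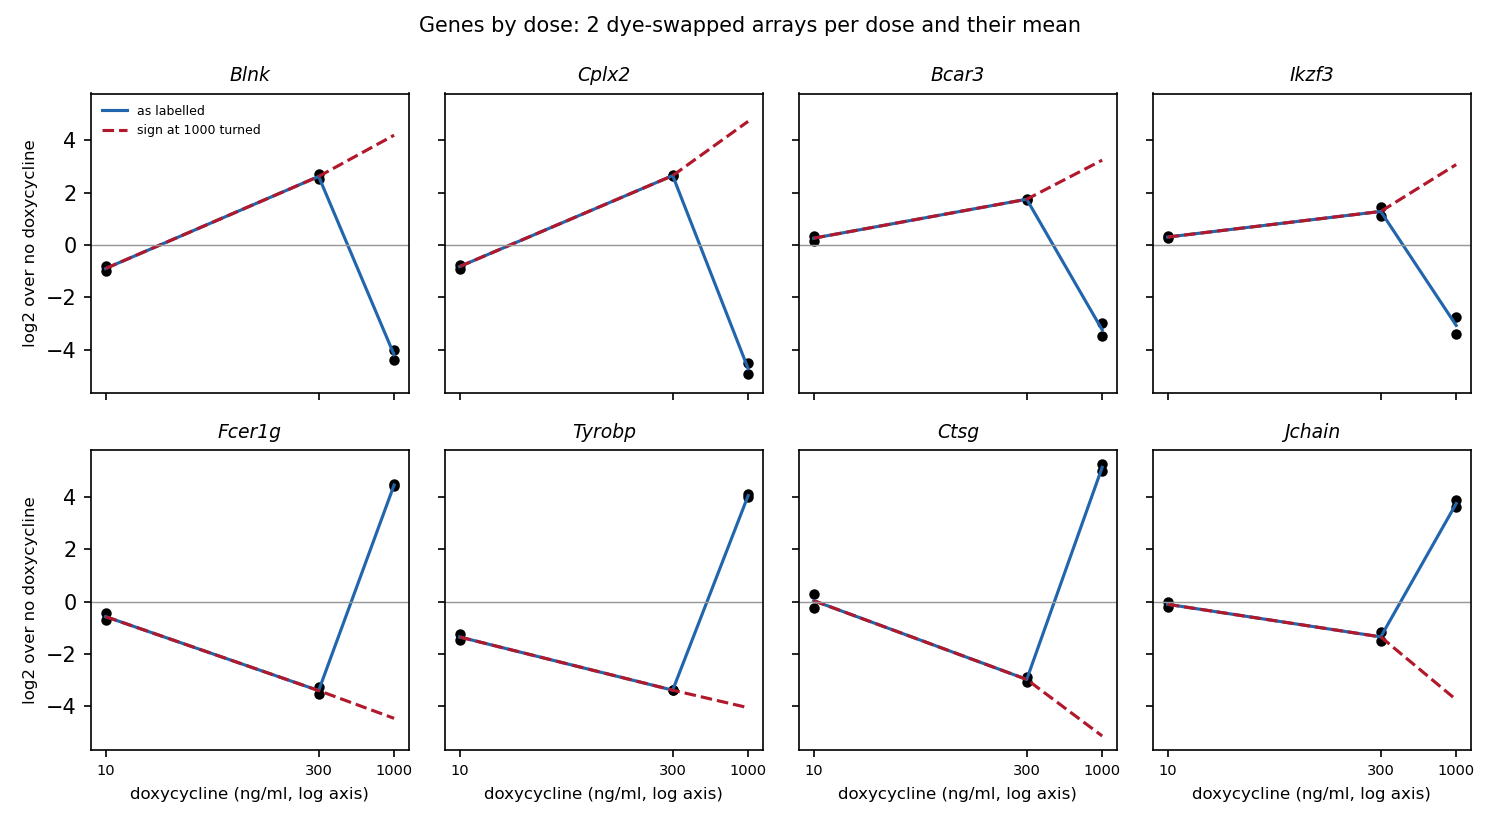
Log2 ratio over no doxycycline (y axis) of 8 genes against dose (x axis, ng/ml, log axis), with each of the 2 arrays as a point, the mean as labelled as a solid line and the mean with the 1000 ng/ml sign turned as a broken line. Blnk has a mean of -0.90 at 10, 2.62 at 300 and -4.20 at 1000 ng/ml as labelled, and Fcer1g of -0.57, -3.40 and 4.46.

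Across the 3 doses, 0 features passed the limma test of a mean doxycycline effect (smallest adjusted p = 0.701). At an unadjusted p under 0.05 there were 1184, where chance gives 1000, but 0 with robust and trended eBayes, 970 with series-matrix ratios and 1897 with arrays as samples. Among the smallest p, none past the threshold, were Socs1, an inhibitor of cytokine signalling (log2 1.20, 1.21 and 1.09 at 10, 300 and 1000 ng/ml), the interferon regulatory factor gene Irf7 (1.11, 1.09 and 1.00), Soat1, which esterifies cholesterol (0.93, 0.83 and 0.80), and the proliferation marker gene Mki67 (-0.87, -0.87 and -0.80). Other probes of Soat1 and Mki67 differed. Mki67 ran against its own list at 10 and 300 ng/ml, where the mitosis genes had medians of 0.17 and 0.29, and -0.71 at 1000 ng/ml. With the 1000 ng/ml sign turned, 0 passed (smallest adjusted p = 0.12) and 4900 had an unadjusted p under 0.05, 1964 higher and 2936 lower. Among the smallest of those were Rtkn2 and the mitotic kinase gene Aurkb, higher, and Cd180 and Pde1b, lower, with other probes of Rtkn2 and Cd180 differing. Without the 1000 ng/ml pair, which is also the value within the later batch, 2816 features passed (smallest adjusted p = 0.0381), 1112 higher and 1704 lower. The 10 and 300 ng/ml ratios are against RNA labelled as the same control, whose own spread this fit leaves out.

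For the dose trend on log10 dose, 0 features passed in limma (smallest adjusted p = 1), and 70 had an unadjusted p under 0.05, where chance gives 1000. That number was 141 with median centring, 283 on dose rank and 1959 on dose in ng/ml. With the sign turned 0 passed and 739 had an unadjusted p under 0.05. None of the trends named here passed. Blnk (-0.90 at 10, 2.62 at 300 ng/ml, and -4.20 at 1000 ng/ml, or its opposite with the sign turned) and Cplx2 had small p upward, and Fcer1g and Tyrobp (-1.35, -3.39 and 4.06, or its opposite) downward, all with the sign turned. On simulated data this test recovered 0% of features at every size of change, so the count of 0 says little.

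In the gene list test (limma camera, correlation preset at 0.01, as labelled), 2 of 18 lists passed, both upward. The interferon response list (adjusted p = 1.01e-09, median mean effect 0.98) and the stromal list (adjusted p = 1.94e-05, median 0.49) passed, but with an estimated correlation neither did (adjusted p = 0.971 for both). On simulated data that setting also missed the 1 list that had been shifted. The interferon medians were 1.12, 1.26 and -0.05 at 10, 300 and 1000 ng/ml, and the stromal medians 0.71, 1.00 and -0.10. Both calls thus come from 10 and 300 ng/ml, which share RNA labelled as the same control, and are no rise at all 3 doses. Adjusted over the list alone, 3 of 17 interferon and 0 of 20 stromal members passed, and 0 over all genes. Adjusted p of the other 16 lists was 0.114 for mitosis, 0.342 for Pax5-activated, pro-B and mature B cell genes, 0.525 for DNA replication, 0.55 for myeloid, 0.768 for Pax5-repressed, 0.799 for amino acid stress, 0.862 for erythroid and p53 target, 0.908 for mast cell, 0.916 for dendritic and stem cell, and 0.951 for T lineage, NK and glycolysis genes. Median and mean differ in sign for the dendritic cell (0.01 and -0.05), NK (0.01 and -0.07), stem cell (-0.01 and 0.02) and glycolysis (-0.01 and 0.01) lists.

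With the 1000 ng/ml sign turned, 9 lists passed the same test, and 0 with an estimated correlation (adjusted p of these lists 0.653 to 0.656). The Pax5-repressed (adjusted p = 3.9e-05, median -0.93), myeloid (0.00328, -0.35) and dendritic cell (0.0478, -0.47) lists fell. The Pax5-activated (adjusted p = 0.00196, median 0.61), mitosis (2.84e-05, 0.37), DNA replication (0.00135, 0.24), amino acid stress (0.000521, 0.42), stromal (3.9e-05, 0.56) and interferon (0.000391, 0.74) lists rose. Passing adjusted over the list alone were 11 of 20 mitosis, 8 of 20 DNA replication, 7 of 17 Pax5-repressed, 6 of 23 myeloid, 5 of 12 dendritic cell and 3 of 18 amino acid stress genes, 0 of the Pax5-activated, stromal and interferon genes, and 0 over all genes. Without the 1000 ng/ml pair 5 lists passed, with the stromal (9.02e-07), interferon (2.21e-09), mitosis (0.0462) and amino acid stress (0.0462) lists up and the Pax5-repressed list down (0.0462), and 0 with an estimated correlation (0.968 for each). Without 10 ng/ml the mitosis (0.00018) and DNA replication (0.0229) lists passed downward as labelled beside the stromal and interferon lists, and 0 with an estimated correlation (0.965). Without 300 ng/ml 8 passed as labelled, with the Pax5-activated (1.97e-06), mitosis (1.09e-05), DNA replication (0.0137) and amino acid stress (0.00552) lists down and the Pax5-repressed (0.000808), myeloid (0.000226), stromal and interferon lists up, and 0 with an estimated correlation (0.65).

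The features past the size at 10 and 300 ng/ml overlapped. Both doses had 91 features higher, where chance gives 1.59, and 184 lower, where chance gives 5.99, with 0 opposite. Among those lower at both were Tyrobp and Cd7, and among those higher Cxcl12 and Ifit1. The ratios correlated with r = 0.795 across genes, with a covariance of 0.161. A control RNA shared by 2 comparisons of equal spread gave by itself, in a simulation, a correlation of 0.5, a covariance of 0.05 and 147 features in the same direction. Its simulated ratios had an SD of 0.316, below the 0.392 and 0.517 of these doses, so the covariance and the count are low for this pair. Of 735 features past the size at 300 ng/ml, 713 had the same sign at 10 ng/ml and 617 were smaller there, and of 375 past it at 10 ng/ml, 373 had the same sign at 300 ng/ml and 187 were smaller there. Selection and a shared control both favour such counts. At 1000 ng/ml 96 of the 735 had the same sign as labelled and 639 with the sign turned. Between 300 and 1000 ng/ml as labelled, r was -0.508 and 194 features were opposite, where chance gives 10.8, Blnk, Fcer1g, Tyrobp and Ctsg among them. With the sign turned 3 were opposite.

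Pax5sz2, which has rtTA but not huPax5, had some of its largest named ratios over clone 4 without doxycycline in genes of B cell receptor assembly. The surrogate light chain genes were higher, with log2 ratios of 7.88 ± 0.94 for Vpreb1, 5.65 ± 0.44 for Igll1 and 4.23 ± 0.35 for Vpreb2. Another probe of Igll1 was at only 0.98. Dntt, the terminal transferase that adds nucleotides at V(D)J joints, was at -4.88 ± 0.32, and the transcription factor genes Foxo1 and Sox4 at -1.66 ± 0.24 and -1.33 ± 0.10. These are 3 higher and 3 lower of 17 pro-B genes (median -0.07, or 0.44 with median centring). Of 20 Pax5-activated genes 2 were higher and 4 lower, with Blnk at -3.41 ± 0.03, Ebf1 at -1.58 ± 0.33 (another probe differing) and Id3 at 1.25 ± 0.14. Of 17 Pax5-repressed genes 2 were higher and 4 lower, with Ccr2 at 3.24 ± 0.30, Jchain at 1.40 ± 0.39 and Notch1 at -1.61 ± 0.18.

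Among lineage lists in Pax5sz2, 3 of 9 NK genes were higher, with Klrd1, which encodes CD94, at 4.58 ± 0.35 and the granzyme gene Gzma at 1.40 ± 0.20. Of 23 myeloid genes 1 was higher and 2 lower (Fcgr3, -4.08 ± 0.15, and Ctsg, -1.69 ± 0.27). Higher were also 3 of 12 dendritic cell genes (Ccr9 at 1.61 ± 0.16), 1 of 18 T lineage genes (Thy1 at 1.68 ± 0.11, another probe differing) and 1 of 20 mitosis genes (Aurka), and the stem cell list had 1 of 12 higher and 1 lower (the endoglin gene Eng at -2.13 ± 0.14). Interferon genes were higher in 6 of 17 (median 0.98, percentile 100), with Usp18 at 2.39 ± 0.05 and Zbp1, a sensor of Z-form nucleic acids, at 1.73 ± 0.12, and stromal genes in 3 of 20 (median 0.18, and 0.17 to 0.58 over 6 other scalings), with Cxcl12 at 1.78 ± 0.12. Amino acid stress genes had 2 of 18 higher (Asns at 1.65 ± 0.083), with a median of -0.19 that was 0.15 with median centring. The p53 target list had 1 of 17 higher and 1 lower (Bcl2l11, which encodes BIM, at -1.59 ± 0.24). No mature B cell, erythroid, mast cell, DNA replication or glycolysis gene passed the size, with medians of 0.03, 0.13, -0.04, 0.04 and -0.16. Median centring gave 0.34 for erythroid, 0.54 for DNA replication and 0.29 for glycolysis genes, and processed signals gave 0.17 for mature B cell genes.

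Other named features higher in Pax5sz2 were Ms4a6b (4.92 ± 0.32), the meiotic cohesin gene Stag3 (4.57 ± 0.22), Slc9a2 (4.18 ± 0.14), the inflammatory caspase gene Casp1 (4.16 ± 0.16), Rangrf (4.05 ± 0.12), Dkkl1 (3.75 ± 0.14), Ifi206 (3.68 ± 0.14) and Xlr4b, at least 11-fold higher over a dim control. Lower were the interferon-inducible gene Ifi202b (at least 15.7-fold, its named RNA being dim), the transcription factor gene Prdm16 (-4.10 ± 0.12), the linker histone genes H1f4 (-3.58 ± 0.15) and H1f3 (-2.93 ± 0.055), the myosin kinase gene Mylk (-2.83 ± 0.071) and the phosphodiesterase gene Pde4b (-2.79 ± 0.21). Another probe of H1f3 differed. In all, 468 features were higher and 564 lower, with r = 0.922 between the arrays across genes. With 300 ng/ml, Pax5sz2 shared 81 higher and 163 lower features (6.15 and 13.3 by chance), at r = 0.457 across genes. Their covariance was 0.125 and 244 features shared a direction. The simulated shared control gave r = 0.5, 0.05 and 147, at an SD of 0.316 where these ratios have 0.517 and 0.528, so sharing beyond the control stays open. The level of the RNA labelled as control differed by over 4-fold in 47 features between these arrays. The simulation's assumption of 1 shared control RNA may thus not hold here. In a limma fit that pools the spread of the doses, 0 passed (smallest adjusted p = 0.0542, 2103 at an unadjusted p under 0.05), and 74 with the 1000 ng/ml sign turned. Median centring gave 479 higher and 203 lower and processed signals 1109 and 1022, with the median of all features at 0.15 under each.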

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

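All tests weighed here were chosen after the results were seen. The first criteria for an exchange of labels and for an opposite effect were correlations of whole channels with the later control channels, and they did not decide: in Cy5 the channel labelled doxycycline had a median of 0.974 (0.959 to 0.978) and that labelled control 0.958 (0.958 to 0.961), in Cy3 0.97 (0.967 to 0.973) and 0.942 (0.94 to 0.964). The first bounds for the interferon levels of the control RNA did not decide either. Later bounds, by which 1 pair of another batch spoke against a low control RNA and against doxycycline, and a stromal count that restated the pattern were replaced as well. The differences between comparisons listed next were not tested, since each comparison is 1 sample.

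Features past the size on both arrays of 2 comparisons in opposite directions numbered, as labelled, 194 for 300 against 1000 ng/ml (10.8 by chance), 36 for 10 against 1000 ng/ml (5.68), 86 for 1000 ng/ml against Pax5sz2 (13.9), 26 for 300 ng/ml against Pax5sz2 (18.5) and 4 for 10 ng/ml against Pax5sz2 (9.35). With the 1000 ng/ml sign turned the first 3 of these counts were 3, 10 and 30. Members of a list that were opposite at 300 and 1000 ng/ml as labelled numbered 7 Pax5-activated, 5 Pax5-repressed, 5 myeloid and 3 mature B cell genes. Among named genes, the log2 ratio at 300 minus that at 1000 ng/ml as labelled was 6.82 for Blnk, 7.38 for Cplx2, 4.95 for Cth, -8.11 for Ctsg, -7.86 for Fcer1g, -7.81 for Gbp8, -7.77 for Nrgn and -7.43 for Spns3. For Il18r1 and Itgb7, whose control RNA at 1000 ng/ml was dim, it was -8.07 and -6.45 with the 1000 ng/ml ratio at its lower bound.

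The first pattern is that the 1000 ng/ml pair runs against the 300 ng/ml pair. The tables argue against a signal tied to the slide or the dye, since the 2 arrays with swapped dyes correlated with 0.829 once turned, though RNA left from an earlier dye-swapped hybridisation was not tested. They also argue against an opposite effect of the highest dose on the same control RNA: the channel labelled control was the nearer to the later control channels in at most 1.55% of the 194 opposite features. An exchange of the 2 RNAs in the labels remains a candidate explanation, as the channel labelled doxycycline was the nearer in 98.5% (Cy3) and 100% (Cy5) of them, at a median log2 distance of 0.312 and 0.271 against 1.72 and 2.01, and the channel labelled control was nearer to the 300 ng/ml RNA in 152 and 162. The 1.55% and the 98.5% are complements within 1 comparison, not 2 separate tests. The control channels of the 300 ng/ml arrays served both in picking these features and in the later control channels compared. That favours these shares to an extent that was not measured, which limits the argument against an opposite effect as well. A different control culture in the earlier batch was not tested, and the direction stays open.

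The second pattern is that interferon genes were higher in 3 named RNAs, at 10 and 300 ng/ml and in Pax5sz2, which by its label has no huPax5 transgene to cause it. A low level in the control RNA of the 6 later arrays stays open: the median log2 level of the earlier channels minus that of the later control channels was -0.0464 in Cy3 and -0.0252 in Cy5, where a low control needs 0.562, but the earlier channels are 1 pair in another batch. Doxycycline itself stays open as well: the size of the list median at 1000 ng/ml minus 0.5 times that at 300 ng/ml was -0.584 (95% of 2000 bootstrap resamples of genes within -0.932 to -0.0893), which speaks against it but rests on that 1 pair, where Irf7 was at 1.00 as labelled, and Pax5sz2 was labelled as treated. At 10 and 300 ng/ml the transgene stays open, as the Pax5sz2 median lay 0.353 above 0.5 times that at 300 ng/ml (-0.462 to 0.562), and culture conditions, which the labels do not give, were not tested.

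The third pattern is that stromal genes were higher at 10 and 300 ng/ml, 16 of 20 on all 4 arrays. More RNA of the OP9 feeder layer in these named RNAs than in the control stays open as a candidate source: it would move feeder genes by about 1 amount, but their mean log2 ratios had an SD of 0.489 over genes (-0.04 to 1.60), against 0.104 between arrays, which the B cells' own expression of such genes or another state of the feeder may cause. The most abundant were Cxcl12 (mean log2 intensity 13.1), Col1a2 (12.9), Col1a1 (11.6), Col3a1 (10.9) and Fn1 (10.6), and 18 of 20 were well above background in the control RNA on all 6 later arrays. The labels name no sort that removes feeder cells. In Pax5sz2 13 were higher on both arrays, and at 1000 ng/ml as labelled 5 were higher and 10 lower, and no biological explanation was tested.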

How the results depend on the processing

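Of the alternatives, those with the 1000 ng/ml sign turned, and an estimated correlation without a dose, were chosen after the results were seen. Counting each main result once per setting, 73 stayed within 1.5 times or on the same side of the threshold and 35 did not. Of the values of named genes 2476 stayed, 74 no longer passed the size and 10 newly passed the test of the mean effect (without 1000 ng/ml). Another 2, not past the threshold of their test, changed sign with the 1000 ng/ml sign turned. A further 1 reversed: Afap1 at 10 ng/ml was 0.41 with the strict filter, which takes another probe. Of list medians and calls 123 stayed, 57 moved (10 of them newly passing), 8 others newly passed and 10 no longer did. The mean effect and the dose trend stayed at 0 features in every setting but those named here. No paired analysis was possible because the replicate number marks the dye orientation of the same RNAs, which the fit with a dye coefficient used, and no culture.

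Processed signals gave 1037 features at 10 ng/ml, 1879 at 300 ng/ml and 2131 in Pax5sz2. Median centring gave 149, 480, 193 and 682 at 10, 300 and 1000 ng/ml and in Pax5sz2, and series-matrix ratios 1053, 1848, 919 and 2169. Scaling to 1 median absolute deviation gave 434 at 300 and 871 at 1000 ng/ml. With the mean of the arrays past the size there were 565 at 10 and 1353 at 300 ng/ml, and with 1.5-fold in place of 2-fold 1670, 2504, 1365 and 2794, since both rules admit more by construction. Single arrays gave 555 to 691 at 10 ng/ml, 1092 to 2260 at 300 ng/ml, 687 to 766 at 1000 ng/ml and 1271 to 1378 in Pax5sz2. For the other settings the cause was not tested.

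Arrays as samples in a random block gave 0 for the mean effect (smallest adjusted p = 0.0905, within-block correlation 0.682). With the sign turned that fit gave 2171 (769 higher, 1402 lower) and, for the trend, 15 (7 and 8), treating technical arrays as samples. Leaving out 1000 ng/ml gave 2816 for the mean effect, and leaving out 10 or 300 ng/ml gave 0. The lists passing numbered 4 without 10, 8 without 300 and 5 without 1000 ng/ml, 0 with an estimated correlation, with or without a dose left out, 9 with the sign turned and 0 with both. For Pax5sz2 the pooled limma fit gave 0, and 74 (56 higher, 18 lower) with the sign turned. For the median mean effect of single lists, processed signals gave 0.075 for T lineage and 0.0647 for glycolysis genes. Median centring gave 0.0428 for T lineage, 0.0572 for dendritic cell, 0.0231 for mast cell, -0.0229 for stem cell and 0.099 for glycolysis genes. The stromal (0.489) and interferon (0.977) medians stayed with an estimated correlation, which ended both calls. It also ended them without 10 (0.403 and 0.757), 300 (0.305 and 0.763) and 1000 ng/ml (0.855 and 1.25).

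With the sign turned, whatever the correlation, list medians were 0.608 for Pax5-activated, -0.927 for Pax5-repressed, -0.353 for myeloid, -0.0471 for T lineage, -0.471 for dendritic cell, -0.0602 for erythroid, 0.0262 for mast cell, 0.238 for DNA replication, 0.368 for mitosis, 0.0534 for p53 target, 0.417 for amino acid stress and 0.0116 for glycolysis genes, and the stromal (0.56) and interferon (0.741) calls ended with an estimated correlation. Leaving out each dose gave medians from -0.758 to 0.315 for Pax5-activated, -0.722 to 0.415 for Pax5-repressed, -0.285 to 0.259 for myeloid, -0.0216 to 0.0395 for T lineage (0.0273 without 10 ng/ml), -0.0246 to 0.183 for NK (0.0147), -0.408 to 0.0996 for dendritic cell, -0.0793 to 0.125 for erythroid, -0.152 to 0.182 for DNA replication, -0.207 to 0.253 for mitosis, -0.246 to 0.234 for amino acid stress and -0.00651 to 0.0436 for glycolysis genes. The 40.4% of spots well above background at the least may limit what the 1000 ng/ml arrays can show, but that call used another multiplier than on the other arrays.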

Other observations

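Fdft1, squalene synthase of sterol synthesis, belongs to no list. It stood among the smallest p of the dose trend, which did not pass, at log2 0.88 ± 0.15 at 10 ng/ml, -0.14 ± 1.17 at 300 ng/ml, -0.57 ± 0.19 at 1000 ng/ml as labelled and 0.80 ± 0.058 in Pax5sz2.

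Dntt was at -0.99 ± 0.027 at 10 ng/ml and 1.04 ± 0.085 at 1000 ng/ml as labelled, with 1 array of each short of the size, and at -2.48 on the 1 array of 300 ng/ml where its spot was not left out. On the Pax5sz2 arrays the mean log2 level of Vpreb1 was 17.8 in the named RNA and 9.92 in the control RNA, while the RNA labelled as the same control had 6.10 on the 10 ng/ml arrays. Igll1 likewise had 14.3 and 8.65, against 6.22 in the control RNA at 10 ng/ml. Between the 10 and 300 ng/ml arrays the control level differed by over 4-fold in 0 features, and between those and the Pax5sz2 arrays in 41 and 47. Between the 1000 ng/ml arrays, of the earlier batch, and the 10 ng/ml, 300 ng/ml and Pax5sz2 arrays it did so in 260, 286 and 193. Whether 1 control RNA served all arrays was not tested. These levels were looked up after the ratios were seen.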
